A study of Oryza sativa with 4 samples.

How the data were processed

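RNA was isolated from 50 mg of frozen roots of rice plants grown for 2 months at 28 °C with 16 h of light and 8 h of dark, and sequenced as 4 libraries: RMh and PhL plants, each with and without Nod factors (NF, 1 nM, 24 h). The submitters' notes name FastQC, Trim Galore 0.3.7 and Bowtie without giving their roles. The genome build, the annotation release and the counting tool are not given in the sources used here. Gene models carry identifiers of the LOC_Os form.

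The authors deposited, for each transcript with at least 1 read, the count of uniquely mapped reads. Per the file headers the values beside it are the transcript length, RPKM and the coverage in percent. The deposited RPKM was checked and equalled the read count scaled by that length and by the library total for every transcript of the 4 libraries. The deposited coverage percent was not used here. Transcripts without a read are not listed and were taken as 0. The 35609 transcripts found in any library belong to 29624 genes, 24848 of them with a single transcript listed, and 15489 genes (52.3%) carry a text naming a function.

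Gene values were sums of RPKM over transcripts, taken as log2(RPKM + 1). A gene counted as expressed in a contrast with RPKM of 1 or more in at least 1 of its 2 libraries, and as differing with 2-fold or more on that scale. Folds of single genes were ratios of summed read counts per library total, with exact (Clopper-Pearson) 95% intervals from the 2 counts. Sequencing reads without molecular identifiers are not independent molecules, so intervals cover counting error only. A gene with 0 reads in 1 library was given a lower bound from a floor of 3 reads in that library. The read depth, 12.4 to 12.6 in units of 1000000 reads, puts 1 read on a 1-kilobase transcript at about 0.08 RPKM.

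The comparisons were PhL_control with RMh_control, RMh_NF with RMh_control and PhL_NF with PhL_control, as the series lists them, plus PhL_NF with RMh_NF and the difference of the NF responses. With 1 library per group no test within a contrast was possible, so these are values and counts. Counting noise was simulated with 20 Poisson draws from pooled means. Contrasts that share a library were set beside simulated unchanged libraries with the same sharing, and overlaps beside those of independent lists.

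Gene lists were fixed before the data were examined: 41 lists, 9 by locus and 32 by words in the function texts. The locus lists hold 69 loci under their published rice names, of which 65 had reads in at least 1 library. For 41 of these the deposited text gives a locus number of the other rice annotation, which equalled the listed one for 39; the 2 others, LOC_Os04g10000 and LOC_Os02g02190, are close copies of a neighbour and carry only their annotation here. Each list's median was ranked among 10000 random lists of the same size drawn within 20 bins of mean expression, and medians outside percentiles 2.5 to 97.5 were called outside the central 95%. Lists for oxygen shortage, further iron deficiency genes, iron storage, EREBP-like factors, UDP-glycosyltransferases, ABC and MATE transporters, aldo-keto and oxophytodienoate reductases, germin-like proteins and glutathione S-transferases outside the chromosome 10 cluster were chosen after the main results were seen. Some text lists are loose, and their members are named where this matters.

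Named genes followed a rule fixed at the same time. It took, per comparison of the series, the 12 highest and 12 lowest differences among genes with RPKM of 5 or more, 20 or more reads in the higher library and a text naming a function. It added up to 4 members of each list that differed 2-fold, the symbiosis and LysM receptor loci whatever their value, and the 5 highest and 5 lowest differences between NF responses. Other genes named, such as LOC_Os09g09210, the genes with reads in 1 line, further list members and the members of the overlap sets, were chosen after their values were seen.

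An additive limma model (line and NF, 4 libraries, 1 residual degree of freedom) tested the line and NF terms under the assumption of equal NF differences in both lines, at a Benjamini-Hochberg adjusted p of 0.05. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter at RPKM 5, a 3-fold threshold, a rescaling of each library to a common sum of RPKM (TPM scale), upper-quartile scaling, trimmed-mean scaling (30% of log ratios and 5% of means trimmed), read counts over library totals, and the highest transcript in place of the sum. Added after seeing the data were leaving a pair of rRNA-derived loci, LOC_Os09g01000 and LOC_Os09g00999, out of the totals, and putting the control library of the other line or RMh_NF in place of a control in doubt. The rRNA-derived pair held 3.07% of the reads in PhL_control, more than in RMh_control (1.67%), RMh_NF (1.66%) and PhL_NF (1.84%).

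Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used. The procedure was tested on simulated data with 200 changed genes: it recovered 99% of 2.5-fold and 100% of 4-fold changes, with 51 further genes at 2-fold from counting noise. The counting intervals covered the true fold in 96% of 1000 draws, and 5% of 200 random lists fell outside the central 95%. On simulated values with an assumed spread of 0.20 (log2), the limma model recovered 100% of 4-fold changes and made 0 false calls. Its power on the real libraries, whose spread is unknown, was not measured.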

Results

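RNA sequencing measured transcript levels in roots of 2 transgenic rice lines that the labels call RMh and PhL. The labels describe the seed as F2 progeny of PhL and of vector control plants, and do not spell out the abbreviations. Plants were grown for 2 months, moved to medium without nitrogen, and kept for 24 h with Nod factors (NF) of Sinorhizobium meliloti at 1 nM or with the detergent CHAPS alone. Nod factors are lipochitooligosaccharide signals that rhizobia release to legume roots. The 4 groups, RMh_control, RMh_NF, PhL_control and PhL_NF, had 1 library each, so there were no replicates and no spread within a group. Every difference described is between libraries, and a difference between libraries is not by itself a difference between conditions. In units of 1000000 uniquely mapped reads, the libraries held 12.5 (RMh_control), 12.4 (RMh_NF), 12.6 (PhL_control) and 12.6 (PhL_NF). Between 27068 and 27270 genes had at least 1 read in a library. Gene levels are the deposited RPKM, summed over a gene's transcripts. Each fold is a ratio of read counts per library total and stands with its exact 95% counting interval, which covers counting error only. The position of a gene list is the percentile of its median log2 difference among 10000 random lists matched on expression, and it describes these libraries.

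The count of genes that differed 2-fold or more was 850 between the lines without NF, 558 with NF in RMh, 905 with NF in PhL and 1280 between the lines with NF. Simulated libraries that differed by counting noise alone gave means of 51.7, 52.1, 50.1 and 48.5 such genes. Of the 41 gene lists, 18, 17, 19 and 20 had a median outside the central 95% of random lists in these contrasts. Chance gives 2.1 if the genes vary independently. Genes of a list can vary together between 2 libraries and lists can share genes, so more may arise without a difference between conditions.

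**Figure D1:**
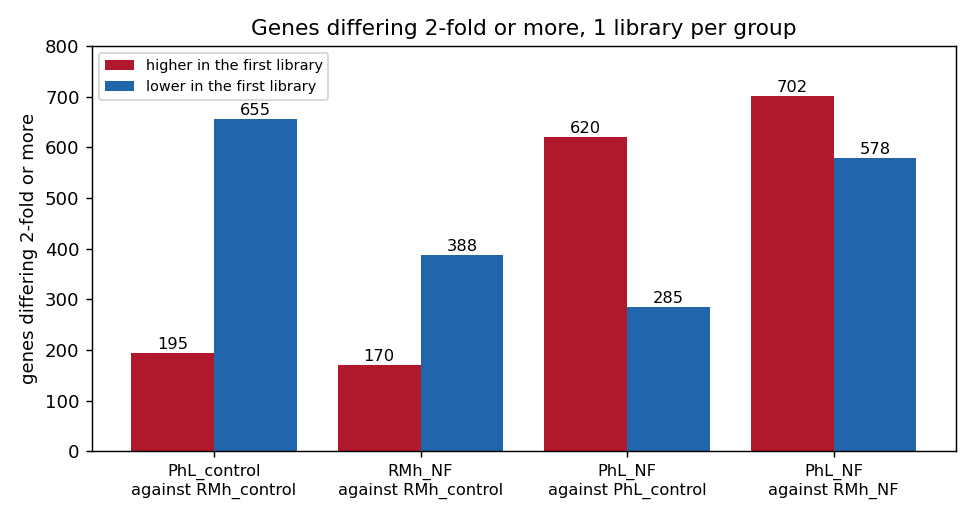
Bars give the number of genes that differed 2-fold or more between the 2 libraries of each contrast (vertical axis, genes), split by direction. PhL_control had 655 genes lower and 195 higher than RMh_control, while PhL_NF had 620 higher and 285 lower than PhL_control.

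The contrast of PhL_control with RMh_control asked which transcripts differ between the lines without NF. Medians of the lists for diterpenoid phytoalexin synthesis, pathogenesis-related proteins, and chitinases and glucanases, which belong to plant defence, lay below the central 95% in PhL_control. So did that of photosynthesis genes, which mark green tissue and not root. Outside the phytoalexin list most members of these lists differed less than 2-fold. A gene annotated as ferredoxin-nitrite reductase, LOC_Os02g52730, was 65.2-fold higher in PhL_control (37.1 to 127), at 28.3 RPKM against 0.435. The annotated cysteamine dioxygenase LOC_Os03g45250 was 33.5-fold lower (23.6 to 49.3), at 1.66 RPKM against 55.8.

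Of 19838 expressed genes, 195 were 2-fold or more higher in PhL_control and 655 lower. The diterpenoid phytoalexin list, whose products are antimicrobial compounds of rice, had 5 of 9 expressed members lower, none higher, and a median log2 difference of -1.07. Its member CYP99A2 was 3.30-fold lower (2.55 to 4.32) and KSL4, which makes the precursor of momilactones, was 4.35-fold lower (2.65 to 7.48). Among 28 pathogenesis-related protein genes 10 were lower and 1 higher, with a median of -0.82. The thaumatin-like gene LOC_Os12g43440 stood at 7.47 RPKM against 30.8. Chitinases and glucanases, which cleave fungal cell walls, had 12 of 35 lower and none higher, with a median of -0.22. Chitinase LOC_Os11g47500 was 10.9-fold lower (8.47 to 14.1) and the glucanase LOC_Os01g71340 was 7.97-fold lower (6.19 to 10.4). Class III peroxidases had 18 of 115 lower and 2 higher, with LOC_Os03g13210 at 77.0 RPKM against 279.

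Of 64 expressed WRKY genes, a family of stress-related transcription factors, 4 were lower and none higher, with a median of -0.21. The list of 7 defence markers had a median of -0.66 and held PR1a at 128 RPKM against 263. EREBP-like factors, which bind ethylene-response elements, had 7 of 70 lower and none higher, with a median of -0.26. This list was chosen after the main results were seen. Its member LOC_Os01g21120 was 12.8-fold lower (10.4 to 15.9). An annotated L-lactate dehydrogenase, LOC_Os06g01590, stood at 0.569 RPKM against 15.2, and the prolyl 4-hydroxylase LOC_Os07g09630 at 2.75 against 39.1. Cytochrome P450 genes had 10 of 108 lower and 3 higher. Medians below the central 95% were also found for 5 iron acquisition genes (-0.51), 14 AP2/ERF genes (-0.36), 10 NAC genes (-0.34), 10 lipoxygenases (-0.32), 10 gibberellin oxidases (-0.42), 31 aquaporins (-0.17) and 25 heat shock proteins (-0.25). The lipoxygenase LOC_Os03g52860 went the other way and was 2.11-fold higher (2.05 to 2.17).

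Medians above the central 95% in PhL_control included those of the nitrogen, ribosomal protein and expansin lists, most of whose members differed less than 2-fold. The list of 15 nitrogen genes had 3 higher and none lower, with a median of 0.19. The members were NAR2.1, the partner protein of high-affinity nitrate transporters, at 82.1 RPKM against 32.9, and the annotated nitrate transporters LOC_Os02g02170 and LOC_Os02g02190, 3.13-fold (2.13 to 4.69) and 3.64-fold higher (2.32 to 5.91). Ribosomal protein genes had a median of 0.23 over 278 genes with no member at 2-fold. Expansins had a median of 0.34 over 13 genes, although Expansin-A17, LOC_Os06g01920, was 2.40-fold lower (2.09 to 2.76). Histone H2A gene LOC_Os07g36130 was 3.04-fold higher (2.78 to 3.32).

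Photosynthesis genes had 11 of 37 expressed members lower in PhL_control, none higher, and a median of -0.39, the same direction as the defence lists. The chlorophyll-binding protein gene LOC_Os01g41710 stood at 24.6 RPKM against 108. RMh_control and PhL_NF stood apart: 170 and 277 genes were 2-fold or more higher in them than in each of the other 3 libraries. The counts were 19 for RMh_NF and 24 for PhL_control. RMh_control stood apart on the higher side only. Lower than in each other library were 20 genes in RMh_control, 13 in RMh_NF, 27 in PhL_control and 103 in PhL_NF. The mean r with the other libraries was 0.969, 0.971, 0.972 and 0.962 in the same order. With RMh_NF in place of RMh_control, an alternative chosen after seeing the data, 529 genes differed, 181 higher and 348 lower in PhL_control. Of them, 263 were shared with the 850. This pair of libraries differs in NF as well as in line. With genes at RPKM 5 or more alone, the nitrogen median was -0.038 and the AP2/ERF median 0.25, and the medians of iron, NAC, lipoxygenase, aquaporin and heat shock genes moved inside the central 95% under at least 1 other setting.

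Lists inside the central 95% in this contrast were strigolactone genes (median -0.21), phosphate starvation genes (0.02), jasmonate synthesis genes (-0.11), LysM domain proteins (-0.13), MYB factors (-0.19), phenylpropanoid and lignin genes (-0.05), glutathione S-transferases (-0.07) and nitrate and peptide transporters (-0.17). The 3 expressed cyclin texts had a median of -0.31, the 6 seed storage texts 0.05, and 161 receptor-like kinases -0.01. The list of NIN-like (RWP-RK) genes matched chaperonin-like and plastocyanin-like texts, and its 8 expressed members had a median of 0.22.

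The contrast of RMh_NF with RMh_control asked which transcripts differ with NF in the RMh line. The median of the iron acquisition list was higher with NF. Nicotianamine is the precursor of the iron chelators that grass roots release, and the nicotianamine synthase genes NAS1 and NAS2 were 18.9-fold (13.7 to 26.7) and 9.84-fold higher (8.36 to 11.6). TOM1, the exporter of the chelator mugineic acid, was 6.47-fold higher (4.36 to 9.92). Most expressed members of the diterpenoid phytoalexin and germin-like lists were 2-fold or more lower with NF. The median of the pathogenesis-related proteins lay below the central 95%, with 9 of 28 members 2-fold lower. The counts were 170 genes higher and 388 lower of 19815 expressed.

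The iron acquisition list had 3 of 5 expressed members higher and none lower, with a median of 2.01. IRT1, an iron uptake transporter, stood at 10.4 RPKM against 10.6. A YUCCA monooxygenase gene, LOC_Os01g25470, had 66 reads with NF and 0 without, at least 22.1-fold higher; YUCCA enzymes make auxin. The annotated jasmonate O-methyltransferase LOC_Os04g56950 was 5.53-fold higher (3.88 to 8.07), the cation transporter LOC_Os01g20160 was 5.11-fold higher (3.80 to 6.97), and the P450 gene LOC_Os08g01450 was 4.32-fold higher (3.71 to 5.04). The nitrogen list had 2 of 15 members higher and none lower, with a median of 0.37. The annotated ammonium transporter LOC_Os02g40730 stood at 32.6 RPKM against 15.2 and nitrate reductase LOC_Os02g53130 at 2.68 against 0.786. Ribosomal protein genes had a median of 0.13, histones 0.13 and aquaporins 0.18.

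Diterpenoid phytoalexin genes had 6 of 9 expressed members lower with NF, none higher, and a median of -1.28. CYP99A2 was 6.59-fold lower (4.67 to 9.53), and CPS2 had 2 reads with NF and 85 without, 42.4-fold lower (11.4 to 356). Pathogenesis-related proteins had none 2-fold higher and a median of -0.55. Chitinases and glucanases had 9 of 35 lower and 2 higher, with a median of -0.14, and chitinase LOC_Os11g47500 was 4.24-fold lower (3.59 to 5.03). The defence markers had a median of -0.61, with PR1a at 112 RPKM against 263. WRKY genes had 6 of 64 lower and none higher. Germin-like proteins, a list chosen after the main results were seen, had 4 of 5 expressed members lower and a median of -2.74. Its member LOC_Os08g08990 stood at 4.26 RPKM against 66.3. The jasmonate synthesis gene AOS2 was 4.25-fold lower (3.41 to 5.33). The sesquiterpene synthase text LOC_Os08g07120 had 1 read with NF and 98 without. NAC genes had a median of -0.38, terpene synthases -0.28, sugar transporters of the SWEET family -0.26 and nodulin-annotated genes -0.40.

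Photosynthesis genes had a median of 0.02 over 36 genes with NF in RMh, inside the central 95%. The lower side of this contrast shares RMh_control with the line contrast. The 2 contrasts had r = 0.56 across genes (0.50 simulated) and 264 genes lower in both, where independent lists give 12.4 and simulated unchanged libraries with the same sharing gave 4.50. Their covariance was 0.105 against 0.0193 in the simulation. Because the simulation holds counting noise only, part or all of the excess may come from the shared library. With PhL_control in place of RMh_control, chosen after seeing the data, 529 genes differed from RMh_NF, 348 higher and 181 lower in RMh_NF. More were thus higher than lower, and 70 of the 529 were among the 558. This replacement mixes the line with NF. The chitinase, WRKY, terpene synthase, aquaporin, SWEET, nodulin, expansin (0.20), cellulose synthase (-0.11) and NBS-LRR (-0.07) medians moved inside the central 95% or turned sign under at least 1 other setting.

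The contrast of PhL_NF with PhL_control asked the same of the PhL line. The median of the iron acquisition list was again higher with NF. NAS1 was 111-fold (74.1 to 176), NAS2 105-fold (78.9 to 143) and TOM1 59.2-fold higher (40.5 to 90.1). Medians of the diterpenoid phytoalexin, glutathione S-transferase, P450 and WRKY lists lay above the central 95% and that of the expansins below it, although outside the phytoalexin list most members differed less than 2-fold. The counts were 620 genes higher and 285 lower of 19768 expressed.

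The iron list had 5 of 6 expressed members higher, none lower, and a median of 3.56. NAAT1, which acts after nicotianamine synthase in chelator synthesis, stood at 8.31 RPKM against 1.15. IRO2, a transcription factor of the iron deficiency response, had 175 reads against 7, 25.1-fold higher (11.9 to 63.3). The remaining member IRT1 stood at 8.48 RPKM against 6.20. Glutathione S-transferases, which conjugate toxic compounds to glutathione, had 20 of 64 higher and 1 lower, with a median of 0.50. LOC_Os10g38340 was 33.0-fold higher (25.5 to 43.3), LOC_Os01g72150 was 10.4-fold higher (8.66 to 12.6) and LOC_Os06g12290, with 125 reads against 0, was at least 41.8-fold higher. P450 genes had 18 of 107 higher and 5 lower, with a median of 0.22. LOC_Os01g43774, annotated to a P450 family that inactivates brassinosteroids, was 76.3-fold higher (57.6 to 103), and LOC_Os09g27510 stood at 99.8 RPKM against 9.47. The annotated aldo-keto reductase LOC_Os04g27060 was 33.2-fold higher (27.2 to 40.8) and the glucosyl transferase LOC_Os01g45110 was 21.8-fold higher (15.1 to 32.6).

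**Figure D2:**
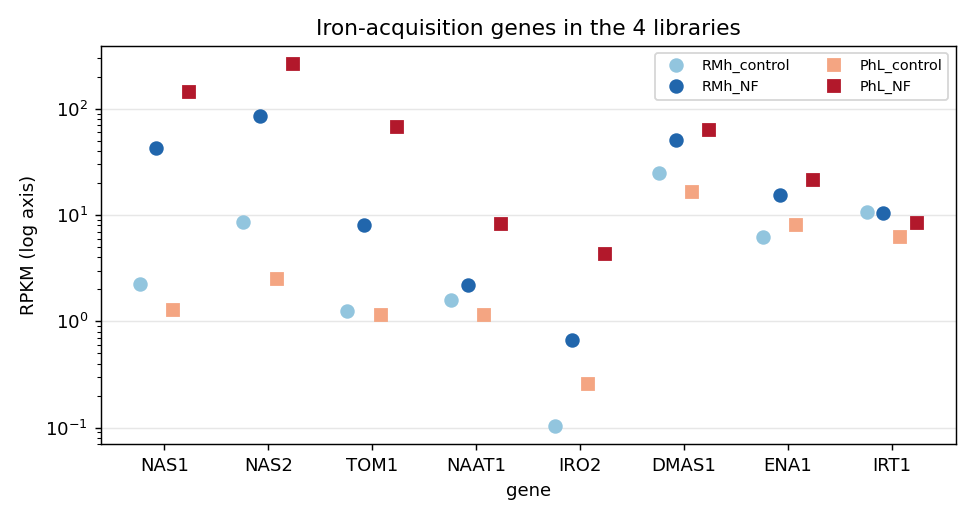
Points give RPKM on a log axis for 8 iron genes in the 4 libraries. NAS2 stood at 8.65 and 85.1 RPKM in RMh_control and RMh_NF and at 2.51 and 264 in PhL_control and PhL_NF, while IRT1 lay between 6.20 and 10.6 in the 4 libraries.

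Diterpenoid phytoalexin genes had 7 of 9 expressed members higher with NF in PhL, none lower, and a median of 1.37. CYP76M7 was 9.71-fold higher (5.79 to 17.4), and CYP99A3 stood at 260 RPKM against 62.1. The list of texts for terpene synthases, which includes enzymes of the same pathway such as the ent-kaurene oxidase LOC_Os06g37224, had 7 of 21 higher, none lower, and a median of 0.51. WRKY genes had 7 of 65 higher and none lower, with a median of 0.36. WRKY45, a regulator of rice defence, was 2.87-fold higher (2.67 to 3.08). The defence markers had 2 of 6 higher and none lower, with a median of 0.92, and the PR10-family gene LOC_Os12g36830 stood at 746 RPKM against 304. Pathogenesis-related proteins had a median of 0.08 over 22 genes, inside the central 95%. Jasmonate ZIM (TIFY) genes, repressors of jasmonate signalling, had a median of 0.68 over 11 genes with 1 member at 2-fold. Lipoxygenases had a median of 0.34, with LOC_Os08g39840 9.58-fold higher (6.03 to 16.0). Histones had a median of 0.26, heat shock proteins 0.22 and NBS-LRR resistance genes 0.13.

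Lower with NF in PhL was the dirigent protein gene LOC_Os12g26380, 33.1-fold (26.3 to 42.1), from a family that guides lignan and lignin coupling. It was lower with NF in RMh also, at 24.2 RPKM against 79.6. Endoglucanase LOC_Os04g57860 was 7.07-fold lower (5.72 to 8.82). Class III peroxidases went both ways, with 7 of 112 higher and 12 lower, and LOC_Os07g31610 stood at 5.58 RPKM against 32.4. Expansins had 5 of 13 lower and 1 higher, with a median of -0.43; LOC_Os03g06020 was 4.60-fold lower (3.54 to 6.05). Cellulose synthases had a median of -0.19 and ribosomal proteins -0.20. The nitrogen list had 3 of 15 lower and none higher, with a median of -0.16, and NAR2.1 stood at 39.5 RPKM against 82.1. Auxin-related genes had a median of -0.11 over 82 genes, with the GH3 gene LOC_Os01g55940 2.06-fold higher (1.91 to 2.22). Response regulator texts, mostly of the ARR-B kind despite the list's name of type-A, had a median of 0.04.

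Photosynthesis genes had 3 of 35 members lower with NF in PhL, none higher, and a median of -0.22, opposite to the phytoalexin and glutathione S-transferase genes. PhL_NF stood apart, with 277 genes 2-fold or more higher and 103 lower than in each of the other 3 libraries. With RMh_control in place of PhL_control, chosen after seeing the data, 1250 genes differed from PhL_NF, 527 higher and 723 lower. Of them, 454 were among the 905. This replacement too mixes the line with NF. This contrast shares PhL_control, with opposite sign, with the line contrast: r was -0.30 (-0.50 simulated), the covariance -0.0675 (-0.0189 simulated), and 150 genes went in opposite directions, where independent lists give 22.5 and simulated unchanged libraries with the same sharing 10.6. Since the simulation holds counting noise only, part or all of the excess may come from the shared library. The nitrogen, auxin, NBS-LRR and heat shock medians moved inside the central 95% under at least 1 other setting.

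The common symbiosis list centres on the signalling pathway that symbiotic fungi and, in legumes, Nod factors use, but not all its genes belong to it. Of its 9 genes, 8 had reads in all 4 libraries, from 1 to 8 reads for the ion channel gene CASTOR. The remaining gene, PT11, was not among the genes with reads. None of the common symbiosis genes and LysM receptors with RPKM 1 or more differed 2-fold on the log2 scale in the 4 contrasts. The calcium- and calmodulin-dependent kinase CCaMK stood at 15.3 (RMh_control), 16.7 (RMh_NF), 15.6 (PhL_control) and 26.6 RPKM (PhL_NF), 1.70-fold higher with NF in PhL (1.5 to 1.93). Its target CYCLOPS was 1.58-fold higher there (1.27 to 1.96) and 1.32-fold higher with NF in RMh (1.04 to 1.67). The receptor kinase SYMRK was 1.03-fold higher with NF in RMh (0.900 to 1.17) and 1.02-fold in PhL (0.888 to 1.16), and both intervals include 1. By read count NSP2, a transcription factor of this pathway, was 2.54-fold higher with NF in RMh (1.36 to 4.97), at 1.77 RPKM. The chitin receptor CERK1 lay between 2.40 and 2.63 RPKM. LYP4, a receptor-like protein that binds chitin and peptidoglycan, was 1.91-fold lower with NF in PhL (1.54 to 2.38). MYR1 had 19, 37, 23 and 14 reads in RMh_control, RMh_NF, PhL_control and PhL_NF. The median of the common symbiosis list was 0.11 with NF in RMh and 0.07 in PhL. That of the LysM receptors was 0.17 in RMh and -0.45 in PhL, the last at percentile 1.66 and inside the central 95% under 3 other settings.

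The contrast of PhL_NF with RMh_NF completes the design, with 702 genes higher and 578 lower in PhL_NF. Diterpenoid phytoalexin genes had 8 of 9 higher with a median of 1.80, iron acquisition genes 5 of 6 higher with 1.64, TIFY genes 4 of 11 higher with 0.95, and glutathione S-transferases 21 of 66 higher and 3 lower with 0.34. WRKY genes had 8 of 65 higher and NBS-LRR genes 12 of 195 higher, none lower in either list. Aquaporins had a median of -0.44 and class III peroxidases -0.23, with 15 of 113 lower and 6 higher. Photosynthesis genes had 16 of 35 lower, none higher, and a median of -0.83. It shares PhL_NF with the NF contrast in PhL: r was 0.70 (0.50 simulated), the covariance 0.186 (0.0189 simulated), and 433 genes were higher in both. Independent lists give 21.2 and simulated ones 4.35. As the simulation holds counting noise only, part or all of the excess may come from the shared library. The contrast and the line contrast without NF share no library. Across genes, which are not independent replicates, r was 0.16 and rho 0.15. In both contrasts 49 genes were higher in PhL and 124 lower, where independent lists give 6.66 and 18.4, and 93 went in opposite directions, where 27.8 would. Independent lists assume that every gene is equally likely to pass 2-fold, which may not hold. The overlap exceeded theirs in the same and in opposite directions, so the excess does not by itself show line differences. The nitrite reductase LOC_Os02g52730 (11.1 RPKM in PhL_NF against 0.690 in RMh_NF), LOC_Os07g36130 for histone H2A and chitinase LOC_Os05g15770 were among the 173 genes with the same direction. An additive limma model, which assumes the same NF difference in both lines, called 1 gene for line. It was LOC_Os09g09210 (log2 difference 6.51, adjusted p = 0.014), higher in both PhL libraries. At an unadjusted p under 0.05 were 1576 genes, 7.66% of the 20563 tested.

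The NF contrasts of the 2 lines share no library either. Their r was -0.10 and rho -0.12. Both had NAS1, NAS2, TOM1 and the annotated major facilitator ENA1 among 16 genes higher, where independent lists give 5.13, and 17 genes were lower in both, where 5.38 would. Chitinase LOC_Os05g15770 was lower with NF in both, at 643 RPKM against 1372 in RMh and 133 against 375 in PhL. In opposite directions went 92 genes, against 14.1 for independent lists. The overlap thus exceeded that of independent lists in the same and in opposite directions. An excess over this baseline does not by itself show an NF difference. Of the 92 genes, 80 were lower with NF in RMh and higher in PhL. By construction RMh_control and PhL_NF are the higher libraries of their lines for these 80, and they are the 2 that stood apart, with 170 and 277 genes 2-fold or more higher than in each other library. The oxygen shortage list, chosen after the main results were seen, differed in the same directions (-0.52 in RMh, 0.79 in PhL), and its member Hb2 was among the 80. These 80 included CPS2, KSL4, CYP99A2, CYP76M7, AOS2, the tyrosine decarboxylases LOC_Os08g04540 and LOC_Os08g04560, the germin-like LOC_Os04g52720 and the WRKY gene LOC_Os01g61080. Among the 12 of the other kind were nitrate reductase LOC_Os02g53130, ferredoxin LOC_Os01g64120 and chitinase LOC_Os04g27980. The limma model called 0 genes for NF, with 710 at an unadjusted p under 0.05 and a smallest adjusted p of 0.762; NAS1 had an adjusted p of 1. The 710 were 3.45% of the 20563 genes tested, under the share of 0.05 that the unadjusted threshold gives without any NF difference. The model's only residual is the difference between the NF responses of the lines, and a large difference there raises p. The low share therefore does not show that NF differences were absent. The difference between the NF responses was 2-fold or more for 1954 genes, 1293 of them in the direction of PhL. It was not tested, since each group had 1 library.

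**Figure D3:**
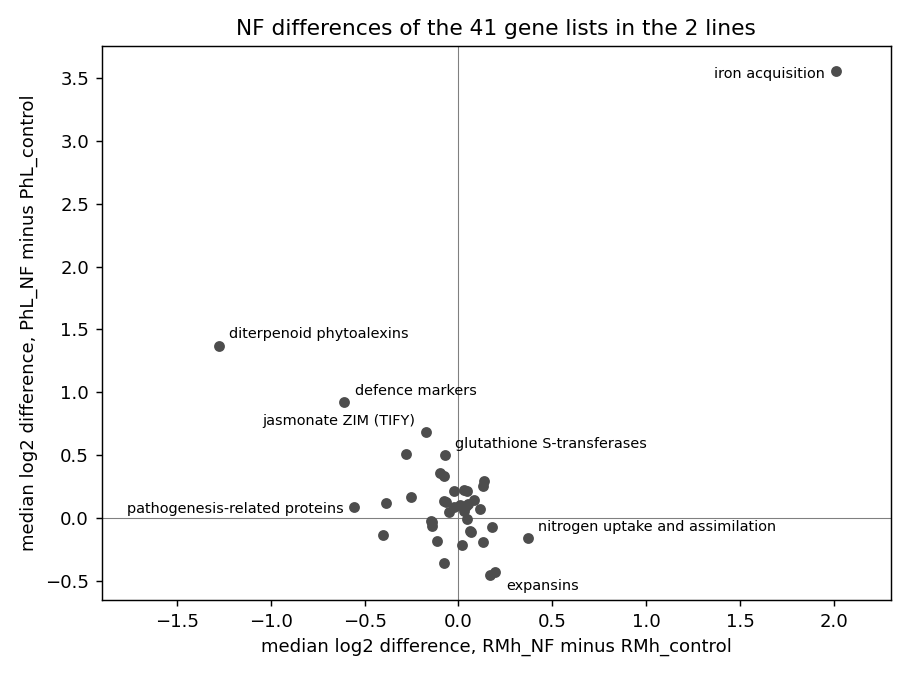
Each point is 1 of the 41 gene lists, placed by its median log2 NF difference in RMh (horizontal axis) and in PhL (vertical axis). The iron acquisition list lay at 2.01 and 3.56, and the diterpenoid phytoalexin list at -1.28 and 1.37.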

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

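The tests of the glutathione S-transferase cluster and of its scaling, and the replacement of RMh_control by RMh_NF, were chosen only after the result was seen.

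The NF difference had opposite directions in the 2 lines for 92 genes at 2-fold or more. Lists whose medians lay outside the central 95% of random lists on opposite sides in the 2 lines differed, PhL minus RMh, by 2.65 for diterpenoid phytoalexins, 1.53 for defence markers, -0.53 for nitrogen genes, 0.45 for WRKY factors, 0.79 for terpene synthases, -0.63 for expansins, 0.20 for NBS-LRR genes and -0.33 for ribosomal proteins, and among lists chosen after the main results were seen by 3.96 for germin-like proteins and 1.31 for oxygen shortage. Single genes whose NF differences had opposite signs in the 2 lines differed, on the log2 scale, by 5.35 (LOC_Os04g27060, aldo-keto reductase), 5.16 (LOC_Os01g22680, cathepsin L text), 4.87 (LOC_Os04g52720, germin-like), 4.84 (LOC_Os10g38340, glutathione S-transferase), -4.43 (LOC_Os01g25030, beta-glucosidase aggregating factor), -4.07 (LOC_Os08g01450, P450) and -3.09 (LOC_Os06g31280, thionin). Of these, LOC_Os10g38340 (-0.10 in RMh, 51 reads against 56, within counting error), LOC_Os04g27060 (-0.53 in RMh) and LOC_Os06g31280 (0.97 in RMh) were under 2-fold in RMh and are not among the 92. Among the lists, WRKY, terpene synthase, expansin and NBS-LRR medians in RMh moved inside the central 95% or turned sign under at least 1 other setting. So did the nitrogen and NBS-LRR medians in PhL, which moved inside it. The differences between the lines were not tested, since each group had 1 library. Most of the 92 genes were high in RMh_control and PhL_NF within their lines, and these are the 2 libraries that stood apart, with 170 and 277 genes 2-fold or more higher than in each other library. CYP99A2 had 9.82 RPKM in PhL_NF and 10.5 in RMh_control, and KSL4 2.61 and 2.49, so the pattern is not separated from the state of these 2 libraries.

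PhL_control had 3.36 genes lower for each gene higher than RMh_control. Composition of the libraries as the cause was argued against, because the ratio stayed at 3.12 or more with trimmed-mean scaling and with the rRNA-derived loci left out. It was lower, at 2.68, with upper-quartile scaling and 2.75 on the TPM scale. Counting noise was argued against as well, since it gave 6.08% as many genes. What stays open is the state of the RMh_control roots, a hypothesis. With RMh_NF in place of RMh_control the ratio was 1.92. RMh_NF also differs by NF, so this replacement cannot separate the state of RMh_control from a difference with NF. Oxygen-shortage genes were 0.50 higher (log2, median of 6 genes) in RMh_control than in the mean of the other 3 libraries. This lay at the bound of 0.5 set for the test. The same list was further from the others in PhL_control, at -0.83, so it does not single out RMh_control, and oxygen shortage in RMh_control may or may not have contributed. A difference between the lines stays open too and was not tested.

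The iron acquisition list was higher with NF in both lines, with medians of 2.01 and 3.56. Reads shared between NAS1 and NAS2 were argued against as the whole cause, because further iron deficiency genes without a nicotianamine synthase had a smaller median of 0.98 across the lines, above the central 95% of random lists; only 3 were expressed, and in RMh 1 of them passed 2-fold and bHLH156 differed by 0.18. Whether the NF-treated roots were in an iron deficiency state cannot be told apart from an effect of NF on these genes, because no more than 2 iron storage genes were expressed in either line, and their values were -0.31 in RMh (1 gene), the direction of iron deficiency, and a median of 0.074 in PhL (2 genes). A difference in the medium or in handling between NF and control tubes may account for the pattern as well and was not tested.

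The glutathione S-transferase list was higher with NF in PhL, with a median of 0.50 and 20 of 64 members 2-fold higher. Reads shared within the chromosome 10 cluster were argued against, because the 39 expressed genes outside it had a median of 0.33 at percentile 100. Library scaling was argued against, as the smaller median under trimmed-mean and upper-quartile scaling was 0.45. For a broad detoxification response, 1 of 3 further lists lay above the central 95%, the ABC and MATE transporters (median 0.17, 11 members 2-fold higher and 1 lower). The bound set before the test, at most 1 list above, was met, and by it the result counts against such a response. The UDP-glycosyltransferases had a median of -0.08 at percentile 0, below the central 95%, with 82 higher and 105 lower at any size and 11 and 6 at 2-fold. The aldo-keto and oxophytodienoate reductases had 7 and 5, and 2 and 0 at 2-fold. Both lists thus held more 2-fold higher than lower members, a condition that was not part of the bound. With it, a broad response cannot be told apart from a difference in this family alone. A difference due to NF in this line may remain, as a hypothesis that 1 library per group cannot separate from the handling of PhL_NF.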

How the results depend on the processing

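The control replacements and the totals without rRNA-derived loci were chosen after seeing the data. Of the summary results under the alternatives, 94 stayed within 1.5 times the main count or within 0.1 of the main correlation, and 23 moved. Counts alone were compared, so a direction could turn. With PhL_control in place of RMh_control, 529 genes differed from RMh_NF, 348 higher and 181 lower in RMh_NF. Of these, 70 were among the main 558. With RMh_control in place of PhL_control, 1250 differed from PhL_NF, 527 higher and 723 lower in PhL_NF. Of these, 454 were among the main 905. Both counts were among the 94, but the larger side turned, and both replacements mix NF with the line. In the order line without NF, NF in RMh, NF in PhL, line with NF and difference of NF responses, the counts were 1542, 1182, 1681, 2267 and 3224 with a pseudocount of 0.1, and 280, 164, 326, 430 and 699 with a pseudocount of 5. At 3-fold they were 252, 155, 284, 371 and 719, a stricter threshold by construction. With genes at RPKM 5 or more they were 531 (line without NF), 336 (NF in RMh), 843 (line with NF) and 1240 (difference), with fewer genes counted by construction. With RMh_NF in place of RMh_control, which mixes NF with the line, the line count was 529. Without a filter 11 lists lay outside the central 95% for NF in RMh; the cause was not tested. The limma model called 1 gene for line where 173 differed 2-fold in both line contrasts, and 0 for NF where 33 did; it has 1 residual degree of freedom.

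Among called list medians 700 stayed, 64 moved inside the central 95% and 4 turned sign. With the RPKM 5 filter the nitrogen median was -0.038 and the AP2/ERF median 0.25 between the lines without NF, and the nodulin median was 0.021 with NF in RMh; that last was 9.2e-05 with no filter. The cause was not tested. Of the differences of single named genes, 503 stayed within their counting intervals and 73 moved, with 0 changes of sign. No paired analysis was possible because the libraries carry no replicate numbers; the exception is the additive limma model above, which pairs libraries by line for the NF term.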

Other observations

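The chromosome segment test was planned before its result was seen; the rules for genes with reads in 1 line and for abundant photosynthesis genes, and the oxygen-shortage and germin-like lists, were chosen only after the main results were seen.

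Some genes had reads in 1 line alone. With 20 or more reads in both libraries of a line and 3 or fewer in both of the other, 13 genes belonged to PhL and 4 to RMh, against 1 gene for the same split by NF and 1 for the crossed split. LOC_Os09g09210 had 2191 and 1734 reads in PhL_control and PhL_NF and 3 and 2 in RMh_control and RMh_NF. LOC_Os01g62740 had 155 and 104 reads in PhL and 0 in RMh, and LOC_Os01g04000 had 96 and 67 in RMh and 0 in PhL. The annotated dienoyl-CoA reductase LOC_Os04g32080 had 63 and 52 reads in PhL and 3 and 3 in RMh.

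Abundant photosynthesis genes were mostly lower in the PhL libraries with and without NF. Of 17 with a mean of 50 or more reads over the libraries, 14 were lower in both PhL libraries than in both RMh libraries and 2 higher, with a median log2 difference, PhL minus RMh, of -1.40. Over all expressed members of the list the medians were smaller, -0.39 without NF (37 genes) and -0.83 with NF (35 genes). Genes of oxygen shortage were lower in PhL_control than in RMh_control, with a median of -0.96 over 6 genes. The pyruvate decarboxylase gene PDC1 was 14.5-fold lower (7.91 to 29.7) and the non-symbiotic haemoglobin gene Hb2 stood at 1.08 RPKM against 53.9. With NF the same list had medians of -0.52 in RMh and 0.79 in PhL. Germin-like proteins had medians of -2.38 between the lines without NF and of 1.22 with NF in PhL.

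A hypothesis was that the 173 genes that differed between the lines both with and without NF lie in chromosome segments inherited by 1 line, as may happen in F2 material. Of these genes, 39.9% had another within 20 expressed genes along the chromosome. Sets of the same size drawn from 557 of the 558 genes that differed with NF in RMh, those with a chromosome position in their identifier, had a median of 35.8%, and the line set lay at percentile 81.5 of these, so segments were not seen by this test. Random sets of expressed genes had a median of 28.3%, and the line set was not ranked among them. The sets of NF genes were themselves more grouped than random sets and come from a contrast that shares RMh_control. The test therefore cannot exclude segments.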
